A study of Rattus norvegicus with 6 samples.

How the data were processed

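Per the labels, 6 libraries of the rat line INS-1E were made: 3 untreated and 3 kept with uric acid (UA) for 24 hours, the group being taken from the sample titles and treatment fields. The labels used here give neither the uric acid concentration nor a vehicle, and do not say whether replicates were separate cultures. Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads, fragmented and copied with dUTP in the second strand, and paired reads of 150 bases were sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR (the last 2 without versions), and give neither the role of each nor the genome build. The strand used for counting is not stated, so values of overlapping or antisense genes are uncertain; 6 of the 73 genes chosen by rule overlap another tested feature, 5 of them one on the other strand.

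The deposited table lists 19289 Ensembl rat features, and per the file headers it has an FPKM column and a count column for each library. Its deposited FPKM values are fragments scaled to transcript length and library total as the authors computed them. Its deposited count columns are estimated counts, checked on the values: each is close to aligned bases divided by 75, rounded up, so that a full pair of reads of 150 bases adds up to 4. Among 3956 small-RNA values, the count implied by FPKM times 75 was a whole number of bases in 68.7% (tolerance 0.05; 10% by chance), and 98.5% of the deposited counts equalled the implied count rounded up. The transcript length implied by count and FPKM differed between libraries by at most 0.21% over 6768 well-covered features. The listed counts are 81.1 to 82.9% of the library totals implied by FPKM. All sample columns were matched to a library. The series-level reference with rat gene names was used only to match older symbols, not for coordinates, which come from the deposited table.

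Features with a mean FPKM of at least 1 over the 6 libraries were tested (12460; 6829 were left out as too low), and uric acid was compared with untreated in edgeR 4.0.16 (quasi-likelihood F test, TMM scaling with factors from 0.992 to 1.009, no covariate) in R 4.3.3. Of the tested features 11626 are protein-coding and 1620 have provisional or no symbols. An adjusted p under 0.05 (Benjamini-Hochberg over all tested features) was the threshold, two-sided. The design fixed before the data were examined assumed that only FPKM were given and named limma on log2(FPKM + 1) as the test. Because the table also holds counts, edgeR was used in its place, and limma 3.58.1 was kept as an alternative (821 features called, 758 of them among the 994 of edgeR). The sample size bounds an exact permutation test of 3 libraries against 3 at p = 0.1, so single values were compared only through models fitted across all genes. Precision was set by the spread between libraries: the common biological coefficient of variation was 0.127, the median standard error of a log2 fold change 0.113, and the smallest change called 0.208.

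Gene lists numbering 32, with 992 genes of which 883 were matched to the table (4 through older symbols), were fixed in advance. Lists with at least 5 tested members were tested with camera (limma) on log2 CPM, counts scaled to the library total (prior count 2) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts adjusted over the list alone were also made. Each of the 5 lists called was called with the preset correlation in 24 of 24 settings. GO and KEGG terms carried by the table were tested with a one-sided hypergeometric test, for terms with 10 to 500 tested members, against 11126 and 4499 tested features with any term of that kind. Named genes were chosen by rule: the 10 largest increases and 10 largest decreases past the threshold with non-overlapping groups and a settled symbol; up to 2 members of each list past the threshold with the smallest p (4 for a list called by camera); and a fixed set of genes of the beta cell, urate handling and stress, whatever their result. Other genes named as members of a list, family or term were chosen after their values were seen.

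The test was tested on simulated data: 200 of 12460 genes were given a change, of which 55.2% were recovered at a log2 change of 0.5, 86.6% at 1 and 100% at 2, with 3 false calls. Alternatives were the pseudocount, the filter (a mean FPKM above 0, or of at least 5), 4 ways of scaling, the model of the spread, the replicate number as a block, only features with settled symbols, a minimum change of 2-fold, the set test, and each library left out in turn. These were planned for limma and applied to edgeR where counts allow. The planned test, limma on log2(FPKM + 1), was run beside them. Chosen after the data were seen were edgeR as the main test and, as alternatives, counts divided by 4, totals implied by FPKM, counts thinned to the smallest library, and DESeq2 1.42.0. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. Reads were not used here, so splicing, strand and assignment to copies were not examined.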

Results

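Messenger RNA was measured in 6 libraries of INS-1E cells, a rat insulinoma line that secretes insulin: 3 from untreated cells and 3 from cells kept with uric acid for 24 hours. The question put by the labels is which transcripts differ in the presence of uric acid. Summed estimated counts were 59092982, 52407439 and 47858248 in untreated libraries 1, 2 and 3, and 48875962, 41191819 and 44849489 in uric acid libraries 1, 2 and 3. A full pair of reads is worth up to 4 of these counts. If every pair added 4, the totals would equal 14773246, 13101860 and 11964562 read pairs in the untreated libraries and 12218991, 10297955 and 11212373 in the uric acid libraries. Between 16590 and 17083 of the 19289 listed features had a count in each library, and 12460 had a mean FPKM of at least 1 and were tested. Ins1 and Ins2, the insulin genes, together held 3.29, 3.56 and 4.03% of the counts in the untreated libraries and 3.73, 3.95 and 3.3% in the uric acid libraries. All listed features of the mitochondrial chromosome together held 7.89, 7.87 and 8.24% against 8.49, 9.1 and 8.28%. Libraries of 1 group correlated at 0.99 to 0.995 (Pearson's r across genes, which are not independent replicates) and libraries of different groups at 0.985 to 0.992. The first principal component held 46.4% of the variance and placed the untreated libraries at -23, -18.2 and -11.1 and the uric acid libraries at 15.7, 33.2 and 3.32, so uric acid library 3 lay nearest to the untreated group.

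Inhbe, Chac1, Trib3 and Atf3 had the largest increases among genes with a settled symbol whose groups did not overlap. Inhbe, which encodes a subunit of activin E, rose from 0.361 ± 0.0951 to 10.2 ± 4.35 FPKM (mean ± SD, n = 3 per group), a 28.2-fold rise. Chac1, an enzyme that degrades glutathione, rose 13.3-fold from 3.86 ± 0.702 to 51.5 ± 5.29 FPKM, and Trib3, a pseudokinase, rose 13.2-fold from 6.37 ± 0.617 to 83.9 ± 30.8 FPKM. The largest decreases were in Slx4ip, which takes part in telomere maintenance and was 4.38-fold lower, and in Bhlha15, a transcription factor of secretory cells (also called Mist1) that fell from 24.3 ± 3.32 to 8.08 ± 1.57 FPKM. Ins1 and Ins2 stayed within the spread of the libraries.

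Log2 fold changes come from edgeR quasi-likelihood fits, with the standard error and the Benjamini-Hochberg adjusted p over all tested features. They were 4.82 ± 0.36 for Inhbe (adjusted p = 0.000211), 3.74 ± 0.15 for Chac1 (5.68e-06), 3.72 ± 0.25 for Trib3 (0.000119) and 3.49 ± 0.24 for Atf3 (0.000138), a stress-induced transcription factor. Slc7a11, the cystine transporter, rose by 3.15 (0.000268), Akna by 2.63, the proto-oncogene Myc by 2.29 (0.00537), Ccdc28a by 2.25 and Crebrf, a regulator of the stress factor CREB3, by 2.08 (5.68e-06). Il23a, a cytokine subunit, rose by 2.46 (0.0139), a call lost without untreated library 2 (adjusted p = 0.0779) or untreated library 3 (0.0552). The Il23a call was also lost with limma without a trend (0.0532) and in quantile-normalized values (0.05). The decreases were -2.13 ± 0.16 for Slx4ip (0.00021), -1.59 ± 0.14 for Bhlha15 (0.000519), -1.37 for Rflnb, -1.28 ± 0.18 for the transcription factor Klf2 (0.0039), -1.28 ± 0.14 for Gmppb, which makes GDP-mannose (0.00155), and -1.13 for Rbm12. Gmppb overlaps Rnf123 on the other strand, and reads of the 2 genes were not separated here. All 3 uric acid libraries lay beyond all 3 untreated libraries in the same direction for every called gene of this paragraph. That was a condition for choosing these genes, so it is no separate evidence. The genome build of the positions is not given in the sources used here. Inhbe (ENSRNOG00000007601) lies on chromosome 7 from 70640075 to 70643169. Chac1 (ENSRNOG00000014387) lies on chromosome 3 from 111160205 to 111163425, and Trib3 (ENSRNOG00000007319) on chromosome 3 from 147813473 to 147819571. Slx4ip (ENSRNOG00000007430) lies on chromosome 3 from 129885826 to 130069390, and Bhlha15 (ENSRNOG00000025164) on chromosome 12 from 12403385 to 12407561.

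Of the 12460 tested features, 622 were higher and 372 lower with uric acid at an adjusted p under 0.05, 994 or 7.98% in all. The median absolute log2 fold change among these was 0.493, and 76 of the higher and 16 of the lower changed at least 2-fold. An unadjusted p under 0.05 was reached by 3199 features, where chance alone would give 623. The groups did not overlap for 3858 features (31%, against 10% by chance for 3 libraries against 3). The p-values measure only the spread between these 6 libraries, because the labels do not say whether replicates of a group were separate cultures. The counts of genes higher in uric acid and genes lower in uric acid moved when 1 library was left out. They were 254 and 104 without untreated library 1, and 165 and 66 without untreated library 2. Without untreated library 3 the counts were 316 and 179, and without uric acid library 1, 224 and 75. In both directions together, 761 features were called without uric acid library 2 and 1173 without uric acid library 3. Fits with 1 library left out have fewer residual degrees of freedom, so a lower count need not come from the library itself. With DESeq2 in place of edgeR 968 genes were higher and 785 lower, and with libraries set to the same sum of FPKM the lower genes numbered 192. Untreated libraries were deeper on average, and after thinning all to the smallest library 953 features were called, of which 925 were among the 994. All 994 kept their sign in every alternative that tested them. Those fits reuse the libraries from which the 994 were selected, so the kept signs are no independent support.

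Targets of ATF4, the transcription factor that answers amino acid shortage and other stresses acting through eIF2alpha, made up the list with the most increases. Of its 30 tested members 24 rose and none fell (26 and 0 adjusted over the list alone), and the median log2 fold change was 1. Its camera test was higher at an adjusted p of 6.16e-27 with a preset correlation (adjusted p = 0.69 with an estimated correlation), and none of the 9 other splits of the libraries gave a p as small. The number of members that rose was 17, 17 and 21 without untreated libraries 1, 2 and 3. It was 18, 24 and 26 without uric acid libraries 1, 2 and 3, and none fell in any of these fits. Atf4 itself rose 2.27-fold from 111 ± 4.3 to 253 ± 28.4 FPKM (0.00021). Amino acid transporters rose: Slc7a1, which carries cationic amino acids, from 13.1 ± 0.721 to 39.7 ± 3.14 FPKM (log2 fold change 1.59 ± 0.08, 1.96e-05). Slc7a5, which carries leucine, rose by 1.01 ± 0.06 (9.29e-05), its partner chain Slc3a2 by 1.46 and the glycine carrier Slc6a9 by 1.45. Sesn2, a leucine sensor that restrains mTORC1, rose by 0.81 ± 0.07 (0.000519), Ddit4, another mTORC1 inhibitor, by 1.10, and the folate enzyme Mthfd2 by 1 on the log2 scale. Gdf15, a stress hormone, rose from 20.5 to 69.8 FPKM (1.77 ± 0.22, 0.00235), and Ddit3, which encodes the death-associated factor CHOP, rose 3.65-fold from 19.3 ± 0.577 to 70.4 ± 26.1 FPKM (1.87 ± 0.23, 0.00226). Ddit3 overlaps Mars1 on the other strand, which itself had a log2 fold change of 0.54. Members that missed the threshold included Asns, asparagine synthetase, at 128 ± 6.16 and 147 ± 18.8 FPKM (0.20, adjusted p = 0.224), Psph at 0.25 (0.354), Pycr1 at 0.38 (0.372) and Wars1 at 0.06 (0.72). Averaged over the 30 members, uric acid libraries 1, 2 and 3 lay 1.24, 1.47 and 0.937 above the untreated mean on the log2 scale, and the untreated libraries between -0.0361 and 0.0253.

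**Figure D1:**
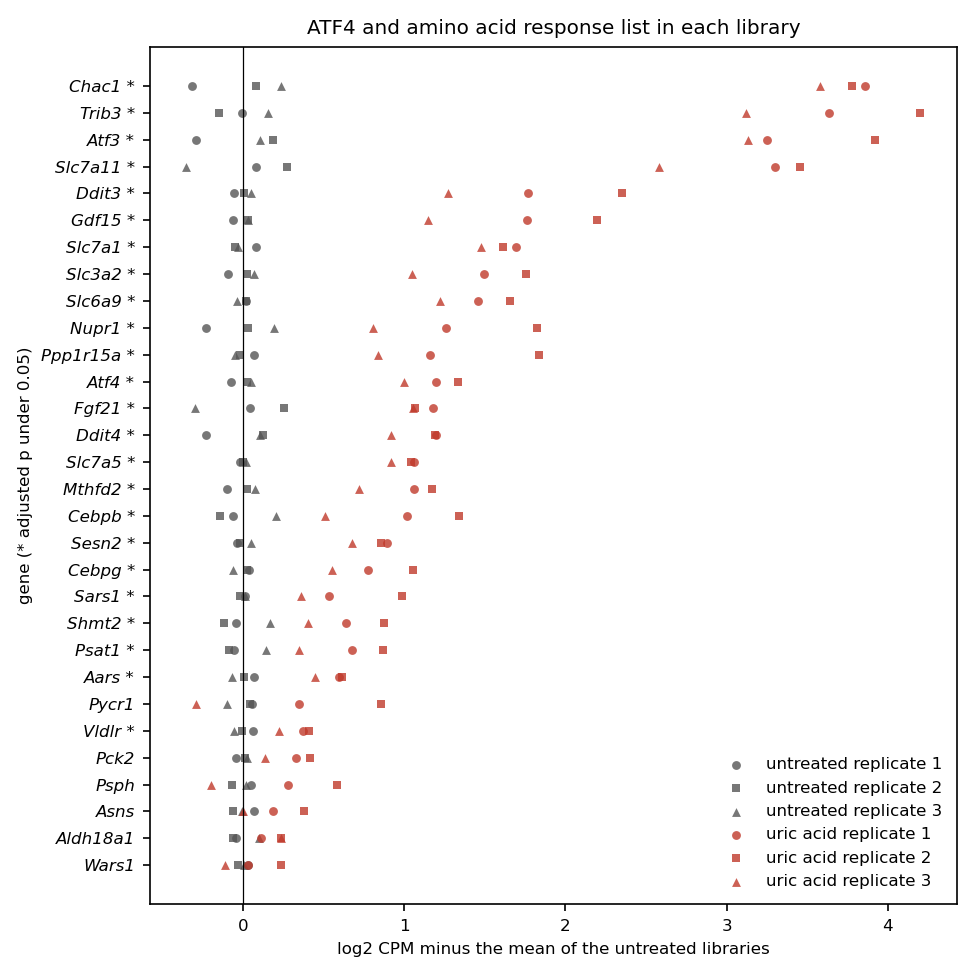
Expression of the 30 tested genes of the ATF4 and amino acid response list in each of the 6 libraries, as log2 CPM (a library-scaled count) minus the mean of the 3 untreated libraries; an asterisk marks an adjusted p under 0.05. The 24 marked genes are higher in uric acid, and uric acid library 3 has the smallest mean shift of its group (0.937).

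Genes of endoplasmic reticulum stress and protein folding moved both ways. Of 31 tested, 3 rose and 2 fell (5 and 14 adjusted over the list alone), with a median of -0.23. Camera called the list lower (adjusted p = 0.0099, adjusted p = 0.749 with an estimated correlation, 0.341 with fry), and 2 of the 9 other splits gave a p as small. Hspa5, the main chaperone of the compartment (BiP), fell from 644 ± 32.7 to 466 ± 40.6 FPKM (27.7% lower, log2 fold change -0.47 ± 0.07, 0.00756), a call lost without untreated library 2 (0.0563). Creld2 fell by 0.50 (0.0294), lost without untreated libraries 1 (0.0855), 2 (0.118) and 3 (0.083) and uric acid library 1 (0.0874), so the number that fell was 1, 0, 1 and 1 in those 4 fits. Ern1, the stress sensor IRE1, rose from 9.56 ± 1.34 to 17.6 ± 2.18 FPKM (0.88 ± 0.12, 0.00328), and Herpud1, which serves the degradation of misfolded proteins, rose by 0.64 ± 0.09 (0.00489). Ppp1r15b, a phosphatase subunit acting on eIF2alpha, rose by 0.45 (0.00769), lost without untreated library 2 (0.0573), where 2 of the list rose. The chaperones Hsp90b1 (-0.24, adjusted p = 0.0695) and Calr (-0.25, 0.0925) missed the threshold, as did the transducers Xbp1 (0.02), Atf6 (-0.02) and Eif2ak3 (-0.10). Hspa5 is ENSRNOG00000018294 on chromosome 3 from 13838304 to 13842762.

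Among heat shock and cytosolic chaperone genes more fell than rose. Of 22 tested, 1 rose and 7 fell (3 and 12 adjusted over the list alone), with a median of -0.19. The 7 include Hspd1, whose protein is a mitochondrial chaperone. The camera adjusted p was 0.000771 (adjusted p = 0.69 with an estimated correlation, 0.0111 with fry), and none of the 9 other splits gave a camera p as small. Hsph1, a nucleotide exchange factor for HSP70, fell from 24.4 ± 1.34 to 15.8 ± 1.69 FPKM (-0.63 ± 0.09, 0.00411) and passed with any 1 library left out. Hspa8, the constitutive HSP70, fell from 352 ± 21.8 to 255 ± 28 FPKM (-0.46 ± 0.08, 0.0133), lost without untreated libraries 2 (0.0812) and 1 (0.0522). Hsp90aa1, an HSP90 gene, fell by 0.39 ± 0.06 (0.00666), lost without untreated library 2 (0.0546). Hspa1b also fell by 0.73 (0.0292), with reads hard to assign because a near-identical copy exists, and its call was lost without untreated libraries 1 (0.101), 2 (0.113) and 3 (0.0685) and uric acid libraries 1 (0.107) and 2 (0.0551). The 1 member that rose was Dnajb4, by 0.44 (0.0384). Its adjusted p was 0.0862, 0.11 and 0.0983 without untreated libraries 1, 2 and 3, and 0.115, 0.0501 and 0.0648 without uric acid libraries 1, 2 and 3, though 2 other members rose without uric acid library 3. The number that fell was 2, 1 and 4 without untreated libraries 1, 2 and 3 and 3 without uric acid library 1.

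Some glycolysis genes fell, and some autophagy and lysosome genes rose. Of 20 glycolysis genes, none rose and 5 fell (2 and 12 adjusted over the list alone), with a median of -0.29. Camera called the list lower (adjusted p = 0.000192, adjusted p = 0.749 with an estimated correlation, 0.219 with fry, and 2 of 9 other splits with a p as small). Pfkfb3, which sets the level of a phosphofructokinase activator, fell from 6.6 ± 0.686 to 4 ± 0.171 FPKM (-0.72 ± 0.10, 0.00463) and passed with any 1 library left out. It was the 1 member called without untreated library 2, untreated library 3 or uric acid library 1, and 1 of 2 without uric acid library 2; 1 member rose without uric acid library 3. Aldoa, an aldolase, fell from 538 ± 63.8 to 404 ± 49 FPKM (-0.41, 0.049), a call that with 1 library left out held only without untreated library 1 (0.0431). It was lost without untreated libraries 2 (0.195) and 3 (0.125), and at 0.0874, 0.0776 and 0.075 without uric acid libraries 1, 2 and 3. Ldha, a lactate dehydrogenase gene held low in beta cells, stood at 0.759 and 1.84 FPKM (1.27, adjusted p = 0.113). Of 40 autophagy and lysosome genes, 7 rose and none fell (9 and 0 adjusted over the list alone), with a median of 0.09. Camera called the list higher (adjusted p = 0.00507, adjusted p = 0.69 with an estimated correlation, 0.0529 with fry, and 1 of 9 other splits with a p as small). Gabarapl1, which builds autophagosomes, rose from 73.1 ± 4.44 to 123 ± 9.32 FPKM (0.75 ± 0.08, 0.00132), and Ulk1, the kinase that starts autophagy, rose by 0.64 ± 0.09 (0.00389). The number of autophagy genes that rose was 2, 3 and 3 without untreated libraries 1, 2 and 3 and 2 without uric acid library 1, Gabarapl1 and Ulk1 among them each time.

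Beta-cell genes changed little as a group: of 34 tested, 2 rose and 3 fell (2 and 4 adjusted over the list alone), with a median of -0.05 and a camera adjusted p of 0.352. Mafa, a factor that drives insulin transcription in mature beta cells, fell from 389 ± 16.8 to 282 ± 29.5 FPKM (27.5% lower, -0.46 ± 0.08, 0.0129). This call was lost without uric acid library 1 (0.071) or untreated library 1 (0.0564) and in quantile-normalized values (0.0641). Mafa is ENSRNOG00000007668 on chromosome 7 from 116780681 to 116781766. Foxa2, a pioneer factor of the endoderm, rose from 45 ± 0.445 to 56.5 ± 2.24 FPKM (0.33 ± 0.06, 0.0175), lost without untreated libraries 2 (0.103) and 1 (0.0629). The other 3 calls, named after their values were seen, were the islet factors Isl1 (-0.29, 0.0282) and Mnx1 (-0.32, 0.031), and the peptide hormone Ucn3, which rose from 112 ± 3.13 to 159 ± 26.1 FPKM (0.0296). Isl1 was lost without untreated libraries 1 (0.101) and 2 (0.134) and uric acid library 1 (0.107). Mnx1 was lost without untreated libraries 1 (0.0797), 2 (0.122) and 3 (0.0901) and uric acid libraries 1 (0.136) and 2 (0.0582), and Ucn3 was lost without untreated libraries 1 (0.0895), 2 (0.135) and 3 (0.075). The list then had 0 members higher and 0 lower without untreated library 1, 0 and 1 without untreated library 2, 1 and 2 without untreated library 3, and 2 and 0 without uric acid library 1.

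Insulin messages did not differ beyond the spread of these libraries. Ins1 stood at 48710 ± 5049 and 49783 ± 6169 FPKM (log2 fold change 0.03 ± 0.11, adjusted p = 0.895) and Ins2 at 18026 ± 1599 and 17717 ± 588 FPKM (-0.03 ± 0.08, 0.859). Reads of these near-identical genes cannot be assigned with certainty. Pdx1, the master regulator of the beta cell, stood at 278 ± 14.6 and 233 ± 15.7 FPKM (-0.26 ± 0.07, 0.0699) and passed without uric acid library 3 (0.0405) and with DESeq2 (0.0228). Slc2a2, the glucose transporter GLUT2, stood at 300.3 and 353 FPKM (0.23, 0.0906), and Txnip, a glucose-induced inhibitor of thioredoxin, had a value of 0.04 (0.898). Among 32 genes of secretory granules and exocytosis, 3 rose and none fell (3 and 0 adjusted over the list alone), and camera gave 0.771. Rph3al, a granule docking factor, rose by 0.39 ± 0.06 (0.00817). The number that rose was 1 without untreated library 2, untreated library 3 or uric acid library 1, and 2 fell without uric acid library 3. Genes that mature beta cells hold low, with immature-cell factors, gave 3 higher and 1 lower of 16 (5 and 1 adjusted over the list alone; camera 0.31). Mycl, a MYC family member, rose by 0.89 (0.00235), Lmo4 rose by 0.73 (0.00817) and Sox9, a factor of ducts and progenitors, fell by 1.07 (0.00828). Myc was the remaining call. The count was 2 higher without untreated library 2, where Lmo4 was lost (0.0546).

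**Figure D2:**
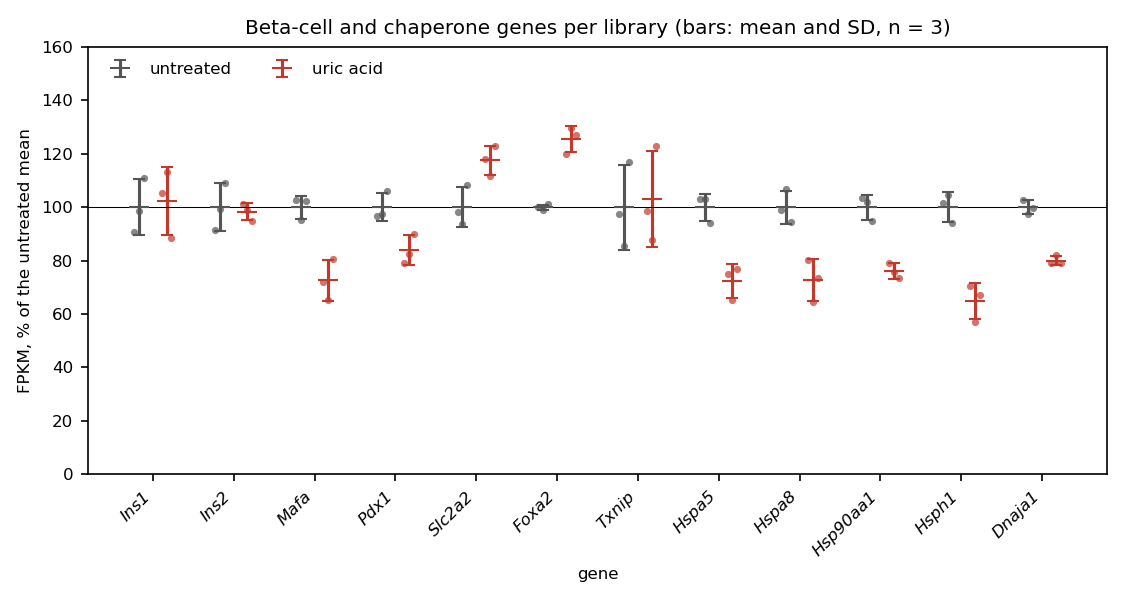
FPKM of 12 beta-cell and chaperone genes as a percent of the untreated mean, with each library as a point and bars for the mean ± SD (n = 3 per group). Mafa (72.5 ± 7.59%), Hspa5 (72.4 ± 6.3%) and Hspa8 (72.6 ± 7.95%) lie below the untreated libraries, and Ins1 (102 ± 12.7%) and Ins2 (98.3 ± 3.24%) overlap them.

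Genes that handle urate or oxidants showed few differences. Slc2a9, the main urate carrier of the liver and kidney, had a log2 fold change of 0.23 (adjusted p = 0.476), and no member of the 5 tested urate transport genes (camera 0.824) or the 21 purine metabolism genes (0.818) passed the threshold. Abcg2, a urate exporter, stood at 0.153 ± 0.0851 and 0.142 ± 0.0656 FPKM, and Xdh, which makes uric acid, at 0.0502 ± 0.023 and 0.113 ± 0.0157, both under the limit for testing. Hmox1 and Nqo1, targets of the oxidant sensor NRF2, had values of -0.16 (0.612) and -0.32 (0.315). Of 28 NRF2 and antioxidant genes, Slc7a11 alone rose, and that gene is also on the ATF4 list. None fell (1 and 0 adjusted over the list alone), and the median was -0.15 (camera 0.147, and called lower without untreated library 1 at 0.0154). Without uric acid library 2, 2 members fell, and without uric acid library 3, 2 rose. Gstp1, another gene of this list, was under the limit for testing, at 0.291 and 1.09 FPKM. In the fit without that limit Gstp1 was higher (1.84, adjusted p = 0.0431). Nos2, the inducible nitric oxide synthase, stood at 0.00296 ± 0.00513 and 0.0142 ± 0.0246 FPKM, and Nlrp3, the sensor of the inflammasome, at 0.189 ± 0.055 and 0.347 ± 0.0806. Il1b is not in the table used here. None of 10 inflammasome genes passed (camera 0.824), though 1 did without uric acid library 3.

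Inflammatory and immediate early genes moved in part. Of 17 NF-kB and inflammatory genes, 5 rose and none fell (5 and 0 adjusted over the list alone), with a camera adjusted p of 0.0655. Camera called the list higher without untreated libraries 2 (0.0436) and 3 (0.0357) and uric acid library 2 (0.0234). Bcl3, a nuclear partner of NF-kB, rose from 1.08 to 2.62 FPKM (1.27 ± 0.20, 0.00785), and Irf1, an interferon regulator, by 0.45 (0.00851), lost without untreated library 2 (0.0621) or uric acid library 1 (0.0501). The number that rose was 2, 1 and 3 without untreated libraries 1, 2 and 3, and 1 without uric acid library 1. Of 24 immediate early genes, 6 rose and 3 fell (8 and 3 adjusted over the list alone; camera 0.0655), with Atf3 and Myc among the higher and Klf2 (16.5 ± 3.71 to 6.76 ± 0.716 FPKM) among the lower. Camera called this list higher without untreated libraries 1 (0.017) and 2 (0.0449) and uric acid libraries 2 (0.021) and 3 (0.0352), with the same FPKM sum (0.0441) and with no filter beyond a mean FPKM above 0 (0.0373). With 1 library left out the higher members ranged from 3 (without untreated library 2 or uric acid library 1) to 8 (without uric acid library 3). They were 4 without untreated library 1, untreated library 3 or uric acid library 2, and the lower members were 1 in all fits but 2 without uric acid library 2. The ERK feedback genes gave 2 higher and 1 lower of 19 (2 and 1 adjusted over the list alone; camera 0.721), and Dusp4, a phosphatase that inactivates ERK, rose by 0.72 ± 0.11 (0.00625). Only 1 ERK gene rose without untreated library 2, untreated library 3 or uric acid library 1, and none fell in any of the 6 fits. The 24 tested genes of the interferon response gave a camera adjusted p of 0.758.

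Cell cycle, death and metabolic lists mostly held few calls. Of 24 p53 targets, 4 rose and 1 fell (6 and 1 adjusted over the list alone; camera 0.712), and Gadd45a, a DNA damage gene, rose by 0.87 (0.00654), while the cell cycle inhibitor Cdkn1a had a value of -0.17 (0.445). The 1 that fell, Ccng1, did so only with all libraries or without uric acid library 2 (0.0393), and was at 0.0829, 0.158, 0.115, 0.107 and 0.0771 without untreated libraries 1, 2 and 3 and uric acid libraries 1 and 3. Of 23 apoptosis genes, 2 rose and 1 fell (3 and 4 adjusted over the list alone; camera 0.818). Bcl2l11, which encodes the death activator BIM, rose by 0.47 (0.00988), lost without untreated library 2 (0.0687) or uric acid library 1 (0.0598), where no apoptosis gene rose; 1 rose without untreated library 1, untreated library 3 or uric acid library 2. Casp9, an initiator caspase, fell by 0.51 (0.0325), lost with any library left out (0.105, 0.0728 and 0.095 for untreated libraries 1, 2 and 3; 0.0874, 0.0631 and 0.0548 for uric acid libraries 1, 2 and 3). For G1/S and DNA replication 0 rose and 4 fell of 40 (2 and 6 adjusted over the list alone; camera 0.072), among them Ccnd3, a G1 cyclin, by 0.48 (0.004). A single G1/S gene fell without untreated library 2, untreated library 3 or uric acid library 1, and 2 rose without uric acid library 3. Camera called the G1/S list lower without untreated library 1 (0.00112) or uric acid library 1 (0.0274), and with no filter beyond a mean FPKM above 0 (0.0352). For G2/M and mitosis 1 rose, the motor protein Kif11, and 1 fell, the separase Espl1, of 41 (1 and 1 adjusted over the list alone; camera 0.424). Kif11 was lost without untreated libraries 1 (0.109), 2 (0.142) and 3 (0.0783) and uric acid library 1 (0.106), and Espl1 without untreated libraries 1 (0.0806), 2 (0.0814) and 3 (0.0715) and uric acid library 1 (0.0948). With all libraries kept, Kif11 passed in 11 of 19 alternatives and Espl1 in 12 of 19. Another G2/M gene rose without untreated library 3, and 2 rose without uric acid library 3.

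Among metabolic lists, the hypoxia response gave 3 higher and 3 lower of 24 (4 and 5 adjusted over the list alone; camera 0.249), with Ddit4 and Pfkfb3 among them. The lower hypoxia genes were 1 without untreated library 2, untreated library 3, uric acid library 1 or uric acid library 2, and the higher 1 without uric acid library 1. Camera called the hypoxia list lower without untreated library 1 (0.0343). Fatty acid genes gave 2 higher and 1 lower of 26 (2 and 3 adjusted over the list alone; camera 0.31). The lipid regulator Srebf1, which overlaps Rai1 on the other strand, fell by 0.31 (0.0199), lost without untreated libraries 1 (0.0573), 2 (0.0904) and 3 (0.0685) and uric acid library 1 (0.0653). No fatty acid gene rose without untreated library 1, 2 or 3 or uric acid library 1, 1 rose without uric acid library 2 or 3, and 2 fell without uric acid library 3. Targets of ChREBP, the glucose-sensing factor, gave 2 higher and 1 lower of 18 (3 and 3 adjusted over the list alone; camera 0.771). Arrdc4, an arrestin relative, rose by 0.39 (0.0088), lost without untreated library 2 (0.0664), where no member was called. The higher ChREBP targets were 1 without untreated library 1, untreated library 3 or uric acid library 1, and none fell without untreated library 1 or uric acid library 1. The 7 acinar and duct genes included 2 that fell, Bhlha15 and Sox9 (0 and 2 adjusted over the list alone; camera 0.0803). No member passed among 62 nuclear-encoded oxidative phosphorylation genes (camera 0.227), 13 mitochondrially encoded genes (0.31) or 69 ribosomal protein genes (0.2). The same held for 24 cholesterol genes (0.31), 10 matrix genes (0.818), 7 histone genes (0.513) and 5 genes of other islet endocrine cells (0.818). With 1 library left out, 1 ribosomal gene rose without untreated library 1 and 1 matrix gene fell without uric acid library 3. Camera then also called oxidative phosphorylation lower without untreated library 1 (0.000149) or uric acid library 2 (0.0074), and cholesterol genes lower without untreated library 3 (0.0054) or uric acid library 1 (0.0274). It called ribosomal genes higher without untreated library 3 (0.0108) or uric acid library 3 (9.99e-05), and in quantile-normalized values (0.00453). These 3 lists also turned in direction without meeting the threshold: ribosomal genes lower without uric acid library 2 (0.135), cholesterol genes higher without untreated library 2 (0.649) or uric acid library 2 (0.806), and oxidative phosphorylation higher without untreated library 3 (0.976). Only 2 of the fibroblast, endothelial and immune genes reached the expression limit, too few for a set test.

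Of the 31 lists with a set test, camera called 2 higher and 3 lower, and with an estimated correlation it called 0 (2 at an unadjusted p under 0.05: the ATF4 list at 0.0471 and the heat shock list at 0.0399). The rotation test fry, which asks whether the genes of a list move on balance one way, called 3, the ATF4, heat shock, and acinar and duct lists. Lists share members, so they are not separate signals. Among genes that rose, Slc7a11 (antioxidant), Sesn2 and Gdf15 (p53), Ddit4 (hypoxia), Fgf21 (ChREBP) and Atf3 (immediate early) are also on the ATF4 list. The median, mean and test differed in sign for 5 lists, none of them called: p53 targets (median -0.05, mean 0.09, test higher), ERK feedback (-0.03, 0.09, higher), apoptosis (0.02, -0.02, lower), inflammasome (-0.01, 0.09, higher) and matrix (0.02, 0.02, lower).

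**Figure D3:**
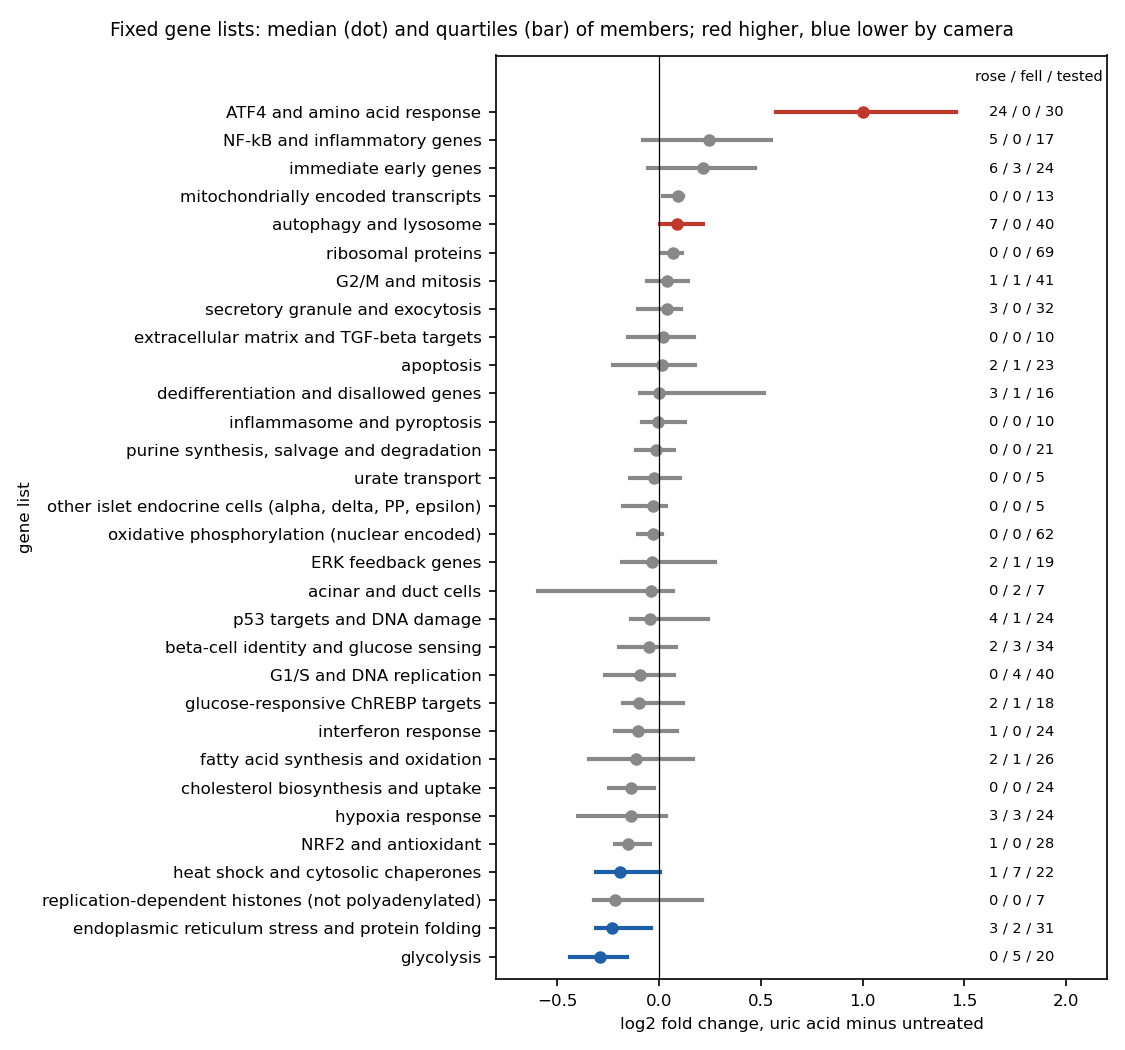
Median log2 fold change (dot) and quartiles (bar) of the tested members of each of 31 gene lists, uric acid minus untreated, with the numbers that rose, fell and were tested; red and blue mark lists that camera called higher and lower with a preset correlation. The ATF4 list stands apart with a median of 1.

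Annotation terms in the table pointed to further groups, chosen after their values were seen. Of 2671 terms tested, 13 were enriched among the higher and 16 among the lower genes (one-sided hypergeometric test, Benjamini-Hochberg). The lower genes held 11 of 26 tested genes of microtubule-based process, 13.3 times the share by chance (adjusted p = 7.8e-07), and 14 of 59 of gap junction (3.59e-05); 9 of the 16 lower terms contain tubulins. Tubb2a, a beta-tubulin, fell from 39 ± 0.927 to 24.2 ± 0.633 FPKM (-0.69, 0.000519) and Tuba1a, an alpha-tubulin, from 584 ± 25.5 to 384 ± 36.4 FPKM (-0.61, 0.00263), with reads of near-identical tubulin copies uncertain in assignment; Tubb5 missed the threshold (-0.19, adjusted p = 0.25). Splicing genes were also among the lower: 15 of 132 spliceosome genes (3.12 times, 0.0219) and 22 of 268 nuclear speck genes (0.0199). Srsf7 fell from 112 to 69.4 FPKM (-0.69, 0.000519) and Srsf2 from 135 to 89.9 FPKM, both serine-arginine splicing factors. The higher genes held 9 of 22 genes of amino acid transport (7.92 times, 0.000697), 47 of 423 with DNA-binding transcription factor activity (0.000682), 10 of 42 aminoacyl-tRNA ligases (0.0199) and 7 of 24 of intrinsic apoptosis in endoplasmic reticulum stress (0.0369). Slc38a2, a neutral amino acid carrier, rose by 1.01 (9.29e-05), Cars, the cysteine tRNA ligase, by 1.03 (0.000957), and Mnt, a MAX partner that opposes MYC, by 1.44. Flcn, folliculin, which acts in nutrient sensing at the lysosome, rose from 14.9 to 36.8 FPKM (1.31, 9.99e-05). Enriched terms numbered 9 without untreated library 2, 14 without uric acid library 1 and 18 without uric acid library 2.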

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

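The features in this part lie outside the comparisons above, because their mean FPKM was under 1; they were tested in the planned fit without that filter, and the floor of 12 counts per library was set after the unit of the counts was seen. Of the 6829 features under the FPKM minimum, 14 passed the threshold in that fit with all 3 uric acid libraries above all 3 untreated libraries and above the floor, a signal in data that the comparisons do not use. Il9r, the interleukin 9 receptor, stood at 0.0313 ± 0.0246 FPKM untreated and 0.606 ± 0.163 with uric acid (log2 fold change 4.24, adjusted p = 0.0031). The others were Gstp1 (1.84, 0.0431), Setdb2 (1.80), Mdfic (1.69, 0.00589), Bcl6 (1.67), Il18rap (1.46), Smim3 (1.42), Arap3 (1.42), Rasgrp3 (1.19, 0.0153), Ccdc180 (1.18), LOC680200 (1.15), Ppargc1a (0.99, 0.0494), Fzd4 (0.93) and Ak9 (0.70). In the opposite direction, 6 features under the FPKM minimum passed with lower values in all 3 uric acid libraries. No floor of counts was applied to these 6, so the 14 and the 6 were not counted by the same rule. No explanation was tested for these features.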

How the results depend on the processing

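Limma on log2(FPKM + 1) was the planned test; edgeR, which took its place, and as alternatives counts divided by 4, totals implied by FPKM, thinning and DESeq2 were chosen after seeing the data, and the other alternatives were planned. All 994 called features kept their sign wherever they were tested, in fits that reuse the libraries from which they were selected. Of 63 named genes past the threshold, 38 stayed past it in every alternative with all libraries that tested them. Genes under a mean FPKM of 5 were not tested at that filter, and the 2-fold minimum was not applied to single genes. In every fit with 1 library left out 33 stayed past the threshold, and 33 did so in both. The genes higher in uric acid (622) became 223 with the replicate number as a block, 968 with DESeq2 and 76 at a 2-fold minimum; the genes lower in uric acid (372) became 99, 785 and 16. The lower genes also became 192 with the same FPKM sum, 242 with that sum taken without the 10 most abundant features and 209 with limma without a trend. Leaving out 1 library gave 165 to 707 higher and 66 to 466 lower. Lists higher (2) became 0 with an estimated correlation and 1 with fry, and 2 to 4 with 1 library left out; lists lower (3) became 0 with an estimated correlation (fry 2), and 3 to 7 with 1 library left out. Lists higher were 4 without untreated library 2 or 3 or uric acid library 2 or 3, and lists lower 7 without untreated library 1 and 5 without uric acid library 1. Enriched terms (29) became 8 at a 2-fold minimum and 17 with camera over the terms, and 9 to 24 with 1 library left out. Replicate numbers do not pair the libraries: the uric acid and untreated deviations of equal number correlated at 0.068, -0.049 and -0.19 across genes, and 1 of 6 libraries correlated best with its own number. The immediate early list, not called (0.0655), was called higher with the block (0.0359). Of the 994 calls, 320 were among the 322 made with the block. Among single named genes, signs turned only in 4 that did not pass the threshold in any fit with 1 library left out. Ins1 ranged from -0.0542 to 0.127 with 1 library left out (-0.04 without untreated library 1, -0.0542 without uric acid library 2), and Ins2 from -0.0912 to 0.0502 (0.0502 without untreated library 3, 0.00117 without uric acid library 3). Txnip ranged from -0.103 to 0.178 (-0.07 without untreated library 2, -0.103 without uric acid library 3), and Hmox1 from -0.317 to 0.0148 (0.0148 without untreated library 2). The fits with a block or a library left out have fewer residual degrees of freedom, and the 2-fold minimum keeps fewer genes by construction; for the other changes the cause was not tested. On simulated data 55.2% of log2 changes of 0.5 were recovered, so features not called may include changes of that size.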

Other observations

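The tests of endoplasmic reticulum stress genes, of dividing cells and of other splits of the libraries were chosen after the result was seen, as were the families of splicing and clock genes. Among 11 tested serine-arginine splicing factors, 4 were lower and none higher (median log2 fold change -0.24). Srsf7 and Srsf2 passed with any 1 library left out, Srsf3 (-0.39) was lost without uric acid library 1 (0.0501), and Srsf1 (-0.28) without untreated libraries 1 (0.0828), 2 (0.111) and 3 (0.0716) and uric acid library 1 (0.0884). Among 19 genes of the circadian clock, 5 were higher and 2 lower. The repressors Nr1d1 and Nr1d2 rose by 1.17 and 0.87, Nfil3 by 1.47 and Ciart by 1.60, and Per2 fell by 0.78, each with any 1 library left out. Arntl rose by 0.80 but was lost without untreated libraries 1 (0.0719) and 2 (0.0951), and Cry1 fell by 0.70 but was lost without untreated libraries 1 (0.0733), 2 (0.069) and 3 (0.06).

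The ATF4 list was higher while chaperones of the endoplasmic reticulum were not. The following checks cover the rise of the ATF4 list alone and do not address the chaperones. The trend of log2 fold change with gene length was weak (Spearman correlation -0.052), so it could explain little of the rise. After that trend was taken out the list's median was 0.987. A shift from a few abundant transcripts is argued against by a median of 1 with the 10 most abundant features left out of the totals. A rise from 1 library alone is argued against by a lowest median of 0.946 over the 6 fits that leave out 1. An unfolded protein response in the endoplasmic reticulum at the time of sampling stays open. The fixed list of its genes had a median of -0.231. From that same list, 22 targets of ATF6 and XBP1 were picked after values were seen. They had 0 higher, 2 lower, 19 negative and a median of -0.245 (upper quartile -0.0923). The pick leaves out Ern1, Herpud1 and Ppp1r15b, the members of the list that rose. Its 0 higher therefore follows from the choice, and the 22 genes are no separate evidence. An amino acid or other eIF2alpha-linked signal may also explain the pattern, and neither it nor an effect of the unstated vehicle was tested.

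Of 15 tested genes with a tubulin symbol 8 fell, 14 had negative values, and the median was -0.422. After the length trend was taken out the median was -0.457. The summed count of these 15 genes was lower by 25.3% (log2 fold change -0.421). It stood at 4262, 4670 and 4766 CPM (library-scaled counts) untreated and 3531, 3131 and 3577 with uric acid. Reads moving among these 15 genes, only some of which are near-identical copies, would leave that sum unchanged. Copies outside the 15 were not summed, so reads moved to them are not covered. LOC100909441, a feature with a provisional symbol that shares terms with the tubulins, is outside the sum and was also lower (-0.45, adjusted p = 0.0105). Fewer dividing cells, as the whole cause, would lower the mitotic genes by about as much, but the G2/M list had a median of 0.0388 (quartiles -0.0572 to 0.143). A part in the fall stays open, since 4 G1/S genes fell and none rose. Only 1 G1/S gene fell without untreated library 2 or 3 or uric acid library 1, and 2 rose without uric acid library 3. The term mitotic cell cycle was enriched among lower genes (12 of 103, 0.0284, 7 of the 12 with a tubulin symbol). Mitotic cell cycle arrest was enriched among higher genes (5 of 12, 0.0435). The number of tubulins that fell was 4 without untreated library 2 and 4 without uric acid library 1, and a change in tubulin message stability or transcription was not tested.

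Aminoacyl-tRNA synthetases of the cytosol lay higher than those of mitochondria. Of 18 cytosolic enzymes 8 rose and 1 fell (Hars1, -0.33, lost without untreated libraries 1, 2 and 3 at 0.0719, 0.0843 and 0.0518 and without uric acid library 1 at 0.0573), with a mean of 0.32; the 17 mitochondrial enzymes had a mean of 0.0172. The difference in means had p = 0.00304 (permutation test over genes, two-sided, 100000 resamples), where genes are not independent. This p describes the difference and tests no cause of it, and 3 of the cytosolic enzymes are on the ATF4 list.

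Splits of the 6 libraries into 3 against 3 number 10, so the share with a result as large is never under 0.1. Each of the 9 other splits mixes both groups on each side, so any difference between the groups widens the spread there. Few calls in those splits are therefore no independent measure of chance. The same limit applies where no other split gave a p as small for a single list. It does not account for other splits with smaller p-values. The smallest unadjusted camera p there was 1.53e-12 for glycolysis, against 1.24e-05 in the real split. It was 2.35e-20 for oxidative phosphorylation (real 0.088) and 5.34e-25 for cholesterol genes (real 0.167). A small camera p at the preset correlation therefore does not by itself mark a difference with uric acid. For genes past the threshold the real split gave 994 and the highest other 1, so 1 of 10 was as large. For lists called by camera the real split gave 5 and the highest other 9, and 8 of 10 were as large. For enriched terms the real split gave 29 and the highest other 0, so 1 of 10 was as large.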
